A study of Hypsibius exemplaris with 12 samples.

How the data were processed

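The series measured gene expression in whole adults of the tardigrade *Hypsibius exemplaris*, a microscopic freshwater animal, after 24 h in bleomycin. Bleomycin is a drug that breaks DNA strands. Each of the 12 libraries came from about 200 animals, with 3 biological replicates for each of 4 groups: animals kept in spring water without the drug, and animals at bleomycin doses of 10 and 100 µg/mL and of 1 mg/mL. Per the labels' protocols, RNA was isolated right after exposure with a column kit and made into strand-specific mRNA libraries.

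The deposited count table gives whole-number read counts per gene for the 12 libraries. Per the file headers, the authors counted reads with featureCounts against the nHd.3.1.5 annotation (a build named for *H. dujardini*, the name this laboratory strain formerly carried). Per the submitters' processing notes its version was 2.0.6. The aligner is not given in the sources used here. The counting command in the header asked for reverse-stranded, paired-end input and for whole gene spans, so introns were included. It set no option for counting read pairs as units, so the 2 reads of a pair entered the counts separately. Of the counts between 1 and 10, 54.3 to 57.6% were even numbers. The mean share was 57.4% in untreated animals and 56.4, 55.6 and 54.9% with increasing dose (n = 3 each). It set no option for reads that map to several places or overlap several genes. Such reads were left out under the counter's defaults, so genes with near-identical copies or same-strand overlaps can be undercounted, and their values are uncertain. The authors also deposited a comparison table for each dose against untreated animals, with log2 fold changes and log2 CPM (counts scaled to a common library size), and with p-values and false discovery rates. The submitters' processing notes name edgeR.

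The count table holds 19700 genes, of which 479 had no read in any library. Total counts ran from 55695250 to 69115127 per library. At this depth 3 counts in a library correspond to well under 1 CPM, and intervals quoted for counts cover counting error only, because reads were not marked by molecule. The replicates are separate samples of animals according to the labels, and no pair of replicates agreed within sampling noise: the mean squared difference over its Poisson variance was 25.4 or more per gene in every pair.

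Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter (16567 of 19700 genes), libraries were scaled by trimmed mean of M values, and all 12 libraries entered 1 quasi-likelihood fit with 8 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 6 comparisons between groups were read from this fit. A slope on log10 dose was fitted to the 9 treated libraries alone. Levels are given as CPM after scaling, as mean ± SD over 3 libraries, and fitted log2 fold changes with their SE. The comparisons between groups and the slope were each tested on simulated data with 200 changed genes. The changed genes all had a mean of at least 5 CPM over the 12 libraries, so recovery at lower levels was not tested. For 10 µg/mL against untreated, over 16138 simulated genes, 31.3% of changes of 1.5-fold, 80.6% of 2-fold and 97% of 4-fold were recovered, with 7 false calls among 146.

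Before the data were examined, the groups, tests, alternatives and a rule for naming genes were fixed. The deposited files give locus identifiers and do not pair them with gene names, and no reference annotation was used here. None of the 21 gene lists that had been set down could therefore be matched (0 of 21), and the tests of those lists were not run. Of the naming rule, the part for unnamed genes remained: for each dose against untreated, the 2 genes with the highest and the 2 with the lowest log2 fold change among called genes with a mean of at least 5 CPM over the 12 libraries and all 3 treated libraries on the same side of all 3 untreated libraries. Coordinates are those of the count table, on the scaffolds of the same build.

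The alternatives were RLE, upper-quartile and library-size-only scaling, no filter or a filter at a mean of 5 CPM, DESeq2 1.42.0, limma 3.58.1 with voom, a block for replicate number, a fit on the 6 libraries compared, a fold-change minimum of 2, a linear dose term, a stricter threshold of 0.01 and leaving out each library in turn. A filter of more than 1 CPM in at least 2 libraries and a fit without the 2 libraries that stand apart on the second principal component were added after seeing the data. Because the comparisons with untreated animals share their control libraries, 20 sets of unchanged groups were simulated. In each set all 12 libraries, the controls included, were redrawn at the untreated mean levels.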

Results

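The study set out to find genes whose transcripts become more abundant in *H. exemplaris* after bleomycin, and compared each of 3 doses with untreated animals. RNA was sequenced from 3 replicates of about 200 animals at each dose. Total counts per library ran from 57761736 to 61610416 in untreated animals, from 63035075 to 63526601 at 10 µg/mL, from 58057943 to 61001658 at 100 µg/mL and from 55695250 to 69115127 at 1 mg/mL (n = 3 each). Levels are given in CPM, a gene's counts scaled to a common library size. The leading principal component held 41.4% of the variance and ordered the groups by dose, from untreated (-49.98 to -34.08) to 1 mg/mL (62.66 to 65.82). On the second (13.2%), untreated replicate 2 lay at -57.14 and 10 µg/mL replicate 1 at -30.26, apart from the others of their groups. Pearson correlations between replicates ran from 0.970 to 0.982 in untreated animals and from 0.989 to 0.990 at 1 mg/mL. The files give genes as locus identifiers without names, so genes are described by identifier, position and level.

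**Figure D1:**
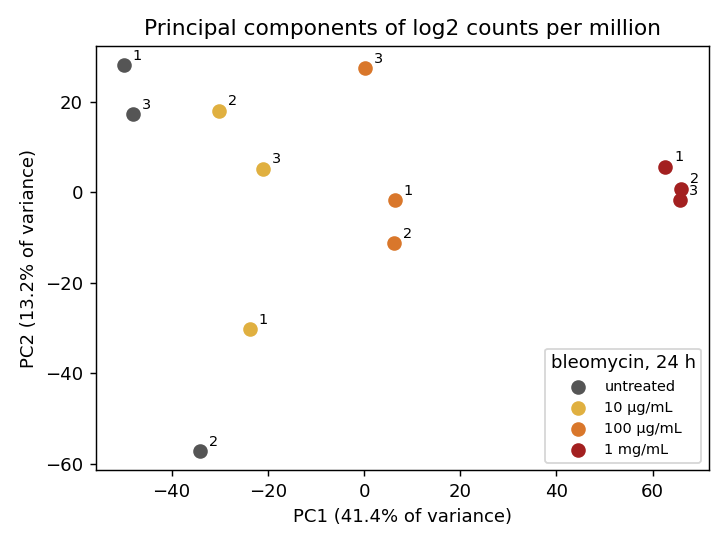
Scores of the 12 libraries on the leading 2 principal components of log2 CPM, coloured by bleomycin dose and numbered by replicate. PC1 (41.4% of the variance) orders the groups by dose, and untreated replicate 2 lies lowest on PC2, at -57.14.

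At 10 µg/mL, the lowest dose, nearly all genes called by the edgeR fit on all 12 libraries went up. Of 16567 genes tested, 114 rose and 1 fell, and the risers had a median change of 2.68-fold. The largest rise was that of BV898_10457, on the minus strand of scaffold0090 (96208 to 97560), which was almost silent in untreated animals at 0.0969 ± 0.0413 CPM and reached 59.4 ± 6.73 (SD, n = 3 each). Its log2 fold change was 9.22 ± 0.19 (SE; edgeR quasi-likelihood test, adjusted p = 8.82e-10). BV898_04740, a short gene on the plus strand of scaffold0024 (139017 to 139379), went from 0.194 ± 0.186 to 11.5 ± 2.00 CPM, a log2 fold change of 5.87 ± 0.37 (SE; edgeR adjusted p = 5.91e-06). Its untreated counts were 6, 24 and 4, and without untreated replicate 2 the log2 fold change was 7.02. The gene that fell was BV898_09375, on the plus strand of scaffold0073 (314503 to 318482), from 87.7 ± 5.48 to 57.7 ± 3.76 CPM (log2 fold change -0.60 ± 0.08 SE, edgeR adjusted p = 0.00494). All 3 treated libraries lay on the same side of all 3 untreated libraries in each of these 3 genes, as the naming rule required.

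The number of genes called at 10 µg/mL depended on the method. DESeq2 called 229, of which 28 fell, and edgeR fitted to the 6 libraries alone called 48, without BV898_09375 (adjusted p = 0.0712). With edgeR on all 12 libraries, 78 of the 114 risers had at least a 2-fold change, and 1016 genes had an unadjusted p under 0.05.

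At 100 µg/mL the calls of this fit included falls as well as rises. In all, 517 genes rose, with a median of 1.65-fold, and 443 fell, with a median log2 fold change of -0.49 (edgeR). A change of at least 2-fold was seen in 190 of the risers and 51 of the genes that fell. BV898_10457 was again the highest, at 226 ± 19.8 CPM (SD, n = 3) and a log2 fold change of 11.15 ± 0.20 (SE; edgeR adjusted p = 8.07e-11). BV898_14064, on the minus strand of scaffold0165 (101993 to 105000), had 2 counts over the 3 untreated libraries and 560 at this dose (3.11 ± 0.807 CPM, with its mean over the 12 libraries carried by 1 mg/mL), a ratio of 271 with a 95% exact counting interval of 74.6 to 2240 (edgeR adjusted p = 3.40e-06). The interval is too narrow, because it takes the reads of a pair as independent. Both untreated counts lay in replicate 1, and without that library the fitted log2 fold change went from 7.85 to 10.58, against a group with no read. Among genes with a mean of at least 5 CPM over the 12 libraries and all 3 treated libraries below all 3 untreated, the lowest fold changes were those of a pair of genes that varied widely among untreated libraries. BV898_15096, on the plus strand of scaffold0196 (119765 to 120366), fell from 21.0 ± 13.4 to 3.47 ± 1.24 CPM (log2 fold change -2.60 ± 0.58 SE, edgeR adjusted p = 0.0263). BV898_10780, on the plus strand of scaffold0095 (91829 to 97768), fell from 15.2 ± 9.95 to 3.18 ± 0.801 CPM (log2 fold change -2.25 ± 0.57 SE, edgeR adjusted p = 0.0444).

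The calls of BV898_15096 and BV898_10780 were lost without 100 µg/mL replicate 1, 2 or 3, without untreated replicate 3, with limma voom and in a fit of the 6 libraries alone. That of BV898_15096 was also lost without untreated replicate 1, and that of BV898_10780 without untreated replicate 2, alone or together with 10 µg/mL replicate 1, with adjusted p up to 0.111 and 0.158 over the alternatives. The count of 960 genes became 1492 with DESeq2, 339 in a fit of the 6 libraries alone, 502 without 100 µg/mL replicate 1 and 559 without replicate 3. The share of calls that rose was 53.9%, and 66.9% when libraries were scaled by size only.

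At 1 mg/mL 38.3% of the genes tested changed, in near equal numbers each way: 3071 genes rose and 3269 fell (edgeR). A change of at least 2-fold was seen in 745 of the risers and 1176 of the genes that fell. BV898_10457 stood at 542 ± 21.8 CPM (SD, n = 3), a log2 fold change of 12.41 ± 0.20 (SE; edgeR adjusted p = 3.32e-11). BV898_14064 had 3761 counts over 3 libraries against 2 in untreated animals, a ratio of 1670 with a 95% exact counting interval of 463 to 13800, again too narrow for paired reads, and a level of 19.2 ± 2.58 CPM (edgeR adjusted p = 8.14e-08). Without untreated replicate 1, which held both untreated counts, its fitted log2 fold change went from 10.47 to 13.19. BV898_00533, on the plus strand of scaffold0002 (611713 to 613746), fell from 198 ± 28.4 to 6.50 ± 1.45 CPM, a log2 fold change of -4.93 ± 0.25 (SE; edgeR adjusted p = 1.17e-07). BV898_15614, on the minus strand of scaffold0215 (19227 to 24134), fell from 355 ± 152 to 8.28 ± 2.01 CPM (log2 fold change -5.42 ± 1.18 SE, edgeR adjusted p = 0.00407), and its level ran from 11.9 to 646 CPM among the libraries at 10 µg/mL.

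The share of calls at 1 mg/mL that rose was 48.4%, and 63.9% with scaling by library size only, which moved the median log2 fold change of all genes from 0.02 to 0.14. Directions at this dose are therefore relative to the scaling, and a minimum change of 2-fold left 1921 of the 6340 genes.

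**Figure D2:**
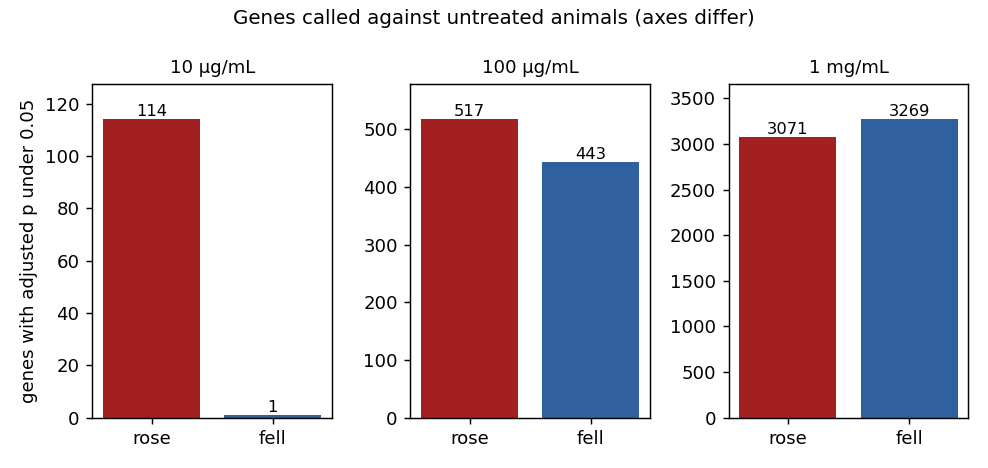
Bars give the number of genes with an edgeR adjusted p under 0.05 that rose (red) or fell (blue) against untreated animals at each dose, on axes that start at 0 and differ between panels. At 10 µg/mL 114 genes rose and 1 fell, while at 1 mg/mL 3071 rose and 3269 fell.

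**Figure D3:**
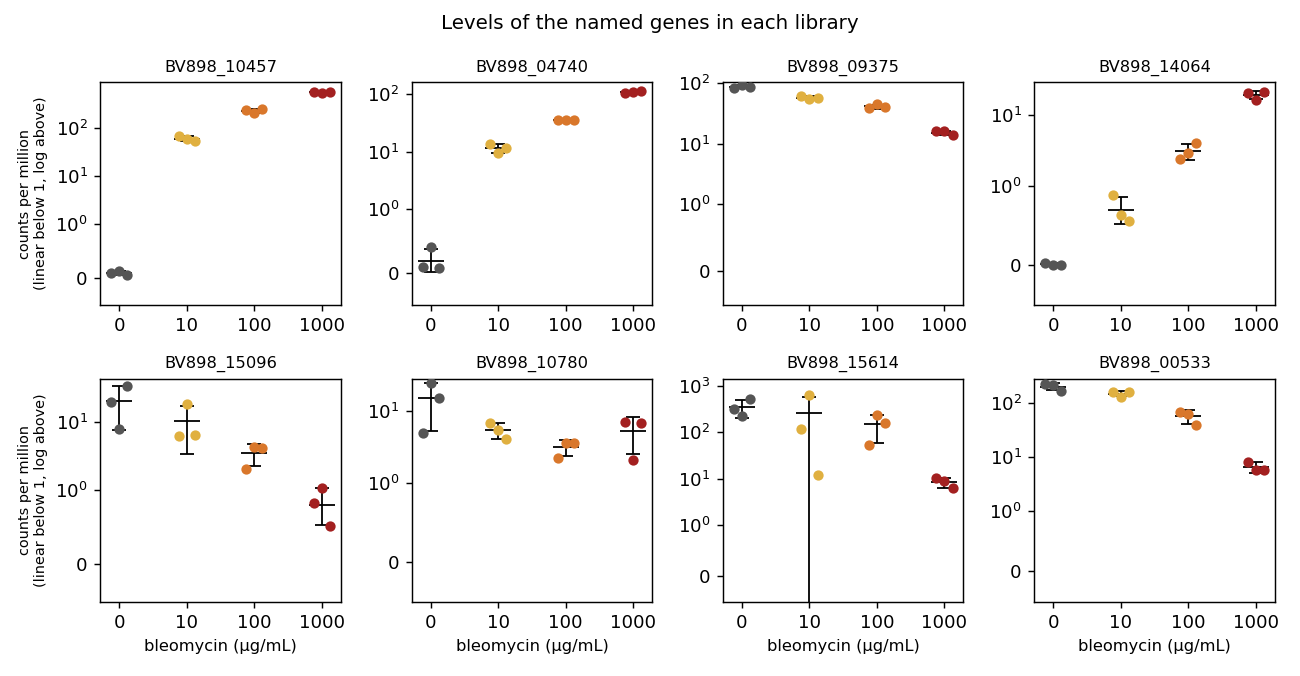
Points give CPM in each library for the 8 named genes against bleomycin dose in µg/mL, on an axis that is linear below 1 and logarithmic above, with horizontal marks at the group mean and bars of ± 1 SD (n = 3). The lower end of the bar for BV898_15614 at 10 µg/mL lies below 0 and is not drawn in full, and BV898_10457 climbs from 0.0969 to 542 CPM.

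Genes that responded to the lowest dose went on responding at the higher ones. Of the 114 risers at 10 µg/mL, 109 also rose at 100 µg/mL and 105 at 1 mg/mL, where 4 fell. Their median change went from 2.68-fold to 5.98-fold and 8.89-fold, and the group means of 80 of them increased at each step of dose. Together they took 0.290 ± 0.0065% of all reads in untreated animals, 0.738 ± 0.034% at 10 µg/mL, 1.48 ± 0.047% at 100 µg/mL and 2.56 ± 0.12% at 1 mg/mL (SD, n = 3 each). The genes were selected at 10 µg/mL against untreated, so their values at that dose are raised by the selection. The same untreated libraries are the reference at the higher doses, so the changes there and the untreated share may be biased by it too. BV898_09375 fell further with each dose, to 41.2 ± 3.1 and 15.2 ± 1.23 CPM. Of the 517 risers at 100 µg/mL, 472 rose at 1 mg/mL and 6 fell. Of the 443 genes that fell at 100 µg/mL, 433 fell at 1 mg/mL. BV898_15096 was among these (edgeR adjusted p = 0.000214), but BV898_10780 was not. The latter stood at 5.38 ± 2.84 CPM at 1 mg/mL (log2 fold change -1.49 ± 0.55 SE, edgeR adjusted p = 0.0537).

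**Figure D4:**
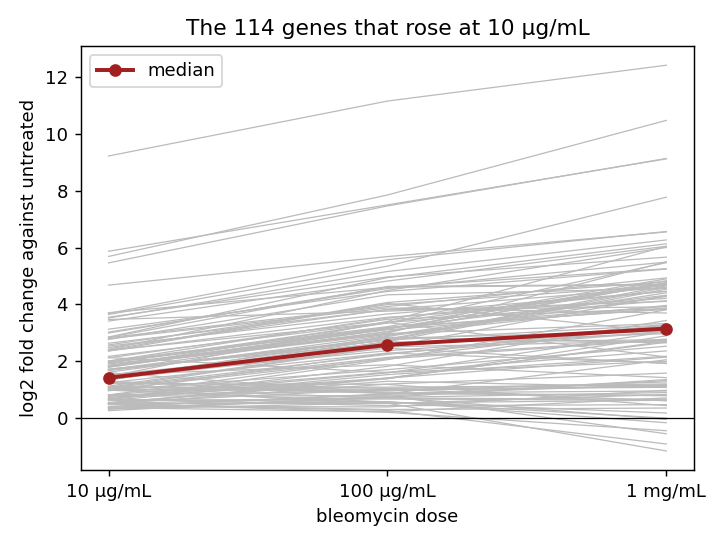
Grey lines follow the log2 fold change against untreated animals (vertical axis) of each of the 114 genes that rose at 10 µg/mL across the 3 doses (horizontal axis), and the red line is their median. The median goes from 1.42 to 2.58 and 3.15, and a few lines end below 0 at 1 mg/mL.

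Independent lists of these sizes would share 3.56 risers between 10 and 100 µg/mL, 21.1 between 10 µg/mL and 1 mg/mL and 95.8 between 100 µg/mL and 1 mg/mL, and for falls 87.4 between the higher 2 doses. Unchanged groups, with all 12 libraries redrawn at the untreated mean levels, shared at most 1 called gene in 20 simulations. Where no gene changes few are called, so this does not show how much shared controls add to lists of these sizes. The 3 control libraries cannot be divided into parts of 2, so part of the excess may come from the shared controls. No library is shared between 10 µg/mL against untreated and the step from 100 µg/mL to 1 mg/mL. Over that step 70 of the 114 risers at 10 µg/mL rose and 11 fell, against 1607 and 2105 of all 16567 genes. Across 12868 genes with a mean log2 CPM above 1, fold changes at 100 µg/mL and 1 mg/mL had a Pearson correlation of 0.813 (0.502 simulated), and their covariance was 0.321 against 0.0312 simulated, a difference of 0.290. For 10 and 100 µg/mL the correlation was 0.791 (0.501 simulated) and the covariance 0.131 against 0.0313, and for 10 µg/mL and 1 mg/mL they were 0.543 (0.496 simulated) and 0.158 against 0.0307. Genes are not independent replicates, so these values carry no p. The simulations drew genes independently, with 1 spread per gene for all groups. Replicates differed most in untreated animals (median SD of log2 CPM 0.142, against 0.0852 at 1 mg/mL). The simulated values may therefore understate what the shared controls add.

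Differences between doses were tested directly. From 10 to 100 µg/mL, 221 genes rose and 201 fell (edgeR). They included BV898_10457, which increased by 1.93 ± 0.12 on the log2 scale (SE; edgeR adjusted p = 8.88e-06), and BV898_00533, with a log2 fold change of -1.39 ± 0.21 (SE; edgeR adjusted p = 0.00684). From 100 µg/mL to 1 mg/mL, 1607 genes rose and 2105 fell. BV898_10457 increased again by 1.27 ± 0.11 (SE; edgeR adjusted p = 2.47e-05), BV898_14064 by 2.63 ± 0.29 (SE; edgeR adjusted p = 9.44e-05), and BV898_00533 changed by -3.12 ± 0.23 (SE; edgeR adjusted p = 9e-06). From 10 µg/mL to 1 mg/mL, 2960 rose and 2996 fell. Across the 9 treated libraries 6126 of 16466 genes had a slope on log10 dose, 3112 upward and 3014 downward. BV898_04740 gained 1.62 ± 0.05 on the log2 scale per 10-fold step of dose (SE; edgeR adjusted p = 1.34e-07).

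The count for the step from 10 to 100 µg/mL also moved with the method and with single libraries. Its 422 genes became 901 with DESeq2 and 206 in a fit of the 6 libraries alone. They became 227, 244 or 154 without replicate 1, 2 or 3 at 10 µg/mL. Without replicate 1, 2 or 3 at 100 µg/mL they became 155, 219 or 178. With scaling by library size only, the share of calls that rose went from 52.4 to 69.6% for this step, from 43.3 to 57.6% for 100 µg/mL to 1 mg/mL, from 49.7 to 67.5% for 10 µg/mL to 1 mg/mL and from 50.8 to 68.9% for the slope.

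The authors' deposited tables hold 14289 genes per dose, the same 14289 genes that exceed 1 CPM in at least 2 libraries. At a false discovery rate under 0.05 the authors' deposited tables call 159 genes at 10 µg/mL (130 up and 29 down), 554 at 100 µg/mL (320 and 234) and 4268 at 1 mg/mL (1745 and 2523). Of the calls in the authors' deposited tables, 99, 473 and 4090 were also called in the same direction by the edgeR fit used here. Conversely, 16, 460 and 1921 genes held in those tables were called here but not by the authors. The direction of the fold change was shared by 97.1% of genes at 10 µg/mL, 98.7% at 100 µg/mL and 99.7% at 1 mg/mL. For BV898_10457 the authors' deposited tables give log2 fold changes of 9.23, 11.15 and 12.41.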

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

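The tests of read depth, of paired reads and of gene span below were chosen after the numbers of detected genes had been seen. A few genes were called in opposite directions at different doses. Of the genes called at both 10 µg/mL and 1 mg/mL, 4 rose at the lower dose and fell at the higher, and for all 4 the difference between these doses was itself called by edgeR. Between 100 µg/mL and 1 mg/mL there were 6 such genes, and the difference was called for all 6. Opposite calls against the same controls nearly fix a difference between the doses, so these tests add little. Picked after their values were seen, as the 2 of the 4 with the largest difference, BV898_05309 on scaffold0028 (293975 to 300024) went from 81.0 ± 3.1 CPM in untreated animals to 161 ± 16.3, 117 ± 12.4 and 36.5 ± 5.22 with increasing dose, and BV898_03139 on scaffold0014 (718286 to 721398) from 49.4 ± 4.95 to 69.4 ± 7.11, 59.7 ± 2.48 and 26.3 ± 1.76 (SD, n = 3 each). The fall from 10 µg/mL to 1 mg/mL was -2.14 ± 0.12 and -1.40 ± 0.10 on the log2 scale (SE, edgeR adjusted p = 3.28e-07 and 1.39e-06). The rises at 10 µg/mL against untreated lay closer to the threshold. Their edgeR adjusted p was 0.00104 for BV898_05309, 0.0447 for BV898_03139, and 0.0369 and 0.0311 for the others of the 4. BV898_03139 was not called at 100 µg/mL (edgeR adjusted p = 0.128).

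Among genes too weakly expressed to be tested, the number detected rose with dose. Of the 3133 genes below the expression filter, libraries thinned to the same total count detected 1129.7 ± 38.9 in untreated animals, 1290.7 ± 47.3 at 10 µg/mL, 1465 ± 72.9 at 100 µg/mL and 1715 ± 51.2 at 1 mg/mL (SD, n = 3 each).

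Over all 19700 genes, the number detected in libraries thinned to 55695250 counts, the smallest total, rose from 17603 ± 46 to 17807 ± 60.8, 18003 ± 83.4 and 18261 ± 50.5 (SD, n = 3 each; exact permutation test of trend over 369600 assignments, two-sided p = 5.4e-06, the smallest it can give). Depth is argued against, because after thinning the lowest 1 mg/mL library still detected 586 genes more than the highest untreated library, with a largest SD within groups of 83.4, and 263 more even when the 1 mg/mL libraries kept 50% of that total, which covers the extreme of paired reads counted separately in untreated libraries alone. Reads running on from risen upstream neighbours are argued against as the main source: of 162 genes silent in untreated animals and detected in all 3 libraries at 1 mg/mL, 10 (6.17%, 95% exact interval 3 to 11.1%) had a risen same-strand neighbour within 2000 bp upstream, against 6 of 190 genes with reads at 10 or 100 µg/mL alone. Background reads spread along the genome, such as from carried-over DNA, cannot be told apart from weak transcription, since both favour long genes and among genes with reads in treated libraries alone, detection in all 3 libraries at 1 mg/mL was 27.8 percentage points higher among the longest 25% of them by span than among the shortest (34.8 against 6.96%). A direct effect of bleomycin dose on weakly expressed genes stays open and was not tested apart from these.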

How the results depend on the processing

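The filter of the deposited tables and the fit without untreated replicate 2 and 10 µg/mL replicate 1 together were chosen after seeing the data. Of 134 counts recomputed under an alternative, 111 stayed within 1.5 times the value reported. DESeq2 gave 229, 1492 and 901 genes for 10 µg/mL against untreated, 100 µg/mL against untreated and 100 against 10 µg/mL, and overlaps of 197 (10 and 100 µg/mL), 190 (10 µg/mL and 1 mg/mL) and 1385 (100 µg/mL and 1 mg/mL). A fit on the 6 libraries compared gave 48, 339 and 206 for those 3 comparisons. Leaving out each library in turn gave 502 to 886 genes at 100 µg/mL against untreated and 154 to 244 for 100 against 10 µg/mL. The cause was not tested for any of these. By construction, a 2-fold minimum lowered the counts to 241 at 100 µg/mL and 1921 at 1 mg/mL, and a threshold of 0.01 lowered the overlaps to 70 (10 and 100 µg/mL) and 364 (100 µg/mL and 1 mg/mL) and the calls shared with the authors' deposited table at 100 µg/mL to 273. Replicate numbers did not pair the libraries: deviations from group means of same-numbered libraries correlated from -0.26 to 0.23, over 0.1 in 2 of 18 pairs, and 4 of 12 libraries correlated best with a library of their own number. With a replicate block the counts were 85, 648 and 5743 against untreated in order of dose, 217 from 10 to 100 µg/mL, 3155 from 100 µg/mL to 1 mg/mL, 5430 from 10 µg/mL to 1 mg/mL and 5399 for the slope, and the call of BV898_10780 at 100 µg/mL was lost (adjusted p = 0.0995). Of 187 recomputed fold changes of named genes, 0 changed sign and 17 lost their call: BV898_10780 in 9 of 17 alternatives (adjusted p 0.00477 to 0.158), BV898_15096 in 7 of 17 (0.000624 to 0.111) and BV898_09375 in 1 of 17 (1.57e-07 to 0.0712). Alternatives for the gene lists were not run, since no list could be matched. Depth limits genes near 0 counts: the log2 fold change of BV898_14064 at 100 µg/mL ran from 7.33 to 10.58 over the alternatives, and at 1 mg/mL from 9.95 to 13.19.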

Other observations

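The summaries by span and expression level and the test of a normalization shift were chosen after seeing the data, and the pattern among neighbouring genes was noticed in it before its tests were set. The test of a normalization shift took the place of one set earlier, on calls under other scalings, which was met but could hardly have come out otherwise, since the scalings differed little at 10 µg/mL. The draws for the slope were raised from 60 to 100 after the result with 60 was seen, which was the same. At 1 mg/mL the direction of change varied with expression level. Of the 3314 most highly expressed genes, the top 20% by mean level, 1198 fell and 565 rose, while of the middle 20% 582 fell and 789 rose. Under RLE scaling the top group held 1240 falls and 526 rises, and under upper-quartile scaling 1037 and 621, but with scaling by library size only rises were the more frequent, at 967 against 891 falls. Within the top group, 43.3% of the 1323 that were also in the longest 20% of genes by span fell, against 31% of the 268 in the shortest 20%. In the other groups by level, from the lowest up, the shares were 4.14 against 9.15%, 16.3 against 17.7%, 18.5 against 21.5% and 24.5 against 22.3%, and none of these differences by span was tested. The typical spread between replicates, as the median SD of log2 CPM over 9883 genes, was 0.14 in untreated animals and 0.09 at 1 mg/mL.

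More genes rose than fell at 10 µg/mL, 114 against 1. The median log2 fold change of the risers lay 1.44 above that of all 16567 genes (-0.02, SD 0.46). Of the 114, 78 rose at least 2-fold. These values cannot decide on a shift from normalization, which would move every gene alike. The risers were selected for a positive change, and the scaling itself centres the fold changes of all genes. Small falls below the threshold may account for part of the imbalance. The step from 100 µg/mL to 1 mg/mL shares no library with 10 µg/mL against untreated. Among the 2105 genes that fell over that step, 60.3% had a negative change at 10 µg/mL. The share was 56.6% of the 12855 genes not called between those doses and 46.4% of the 1607 that rose. The excess over the genes not called is too small to decide. DESeq2 called 28 falls among 229 genes, so the size of the imbalance depends on the test. A selective rise at low dose stays open and was not tested apart from a shift or from small falls.

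Neighbouring genes on a scaffold changed together at 1 mg/mL. The rank correlation of their log2 fold changes, across gene pairs that are not independent replicates, was 0.24 for 8080 same-strand pairs, 0.15 for 3940 divergent pairs and 0.05 for 3955 convergent pairs, and at most 0.04 for same-strand pairs in 1000 shuffles of gene order; at 100 µg/mL the values were 0.182, 0.128 and 0.0641, and at 10 µg/mL 0.0983, 0.122 and 0.0224. Same-strand pairs over 5 kb apart exceeded convergent pairs at any distance by 0.144 (95% bootstrap interval 0.0703 to 0.218). This cannot decide on reads running on into the next gene, because such reads also favour same-strand pairs and their reach was not tested. Over 5 kb apart, the correlation was 0.198 for same-strand pairs (95% bootstrap interval 0.133 to 0.263). It was 0.0515 for divergent pairs (-0.0324 to 0.137) and -0.0191 for convergent pairs (-0.15 to 0.106) at that distance. For the 1017 same-strand pairs under 500 bp apart or overlapping, with a correlation of 0.577, run-on reads or divided gene models could add to the correlation. A general tendency of neighbours to vary together cannot be told apart, since correlations were present at 10 µg/mL, where 115 genes were called, and differences between replicates of a group gave correlations up to 0.164 and noise lowers such values. Shared regulation after bleomycin is a hypothesis that stays open, untested here.

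Other ways of dividing the libraries gave fewer calls. Real and other splits of the 6 libraries compared were fitted alike, with the other 6 libraries kept in the fit under their own groups. For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and the real split was the only 1 of the 10 with as many calls: 115 genes against a highest other of 15 at 10 µg/mL, 960 against 21 at 100 µg/mL and 6340 against 0 at 1 mg/mL. Between doses the values were 422 against 8 for 10 to 100 µg/mL, 3712 against 0 for 100 µg/mL to 1 mg/mL and 5956 against 0 for 10 µg/mL to 1 mg/mL. Every other split mixes libraries of both groups, so an effect of dose would widen the spread within groups and lower its calls. The counts of other splits therefore do not show what a division gives where no effect is present. For the slope, 100 assignments of dose to the 9 treated libraries were fitted, the real one and others drawn at random from a larger number of possible ones. Assignments that swap the lowest and highest dose of one already drawn, the real one included, were left out, since they give the same count. Of these 100, the real one alone reached 6126 genes and the highest other reached 225. Assignments not drawn were not fitted, and an effect of dose would widen the spread in the other assignments too.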
